A study of Mus musculus with 15 samples.

How the data were processed

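The series measured RNA from the choroid plexus of 15 mice on the C57BL/6J background, all labelled male and 3 weeks old, with 5 wild-type, 5 heterozygous and 5 null animals for Add1, which encodes the actin-capping membrane skeleton protein alpha-adducin. Per the labels' protocols, tissue was put into Trizol, RNA was extracted with a column kit for small samples, and 250 ng of total RNA was labelled with biotin by a whole-transcript expression kit. Each animal gave 1 single-colour Affymetrix array.

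The deposited table holds 1 value per probe set and array for 35556 probe sets. Per the submitters' processing notes, Affymetrix Expression Console 1.1 and RMA were used; RMA corrects the background, normalizes quantiles between arrays and summarises the probes of a set, so small differences in total signal between arrays are removed. The deposited values are taken to be on the log2 scale. The log base is not given in the sources used here and was read from the values, which run from 1.57 to 13.89 with 2 decimals and have array medians between 4.78 and 4.88. The genome build, the probe annotation used by the submitters and the deleted part of Add1 are not given in the sources used here. For arrays, the number of animals limits the precision, and the log2 difference of a gene near the background is compressed.

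Probe sets were named from the platform annotation, which can be old. It listed 23410 of the probe sets, 21789 of them with 1 gene symbol and 1621 with several; 12146 were not listed and stay unnamed here. Of those with 1 symbol, 21698 had their gene identifier in the reference gene table of GRCm38.p6, which was used only for names and for the order of neighbouring genes. For each of the 19938 genes the probe set with the highest mean over the 15 arrays was kept; 999 genes had more than 1. Genes were tested if their value exceeded 5.33, the median of all values of these probe sets, in at least 5 arrays, which left 10069 genes.

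Groups were taken from the genotype label of each sample. All 15 arrays entered 1 linear model per gene in limma 3.58.1 (lmFit and eBayes, R 4.3.3), with 12 residual degrees of freedom before moderation and no covariate. The contrasts were null against wild type, heterozygous against wild type, null against heterozygous, and the heterozygous mean against the midpoint of the other genotypes. The slope on the number of wild-type Add1 alleles came from a separate linear model over the same arrays, with that number as predictor. Benjamini-Hochberg adjusted p-values under 0.05 were called. Levels of Add1 were also compared with an exact two-sided permutation test over the 252 regroupings of 5 against 5 arrays, whose smallest possible p is 0.00794.

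Before the data were examined, 25 gene lists of pathways and cell types were fixed, and 23 of them had members above the filter; the lymphocyte and neutrophil lists had 0. Lists were tested with limma's camera with a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, and p-values were adjusted over the 23 lists of a comparison. Add1 itself was left out. The genes named were also fixed by rule before the data were examined. For each pair of genotypes they are Add1, then the 12 largest rises and the 12 largest falls among called genes, or the 10 smallest p-values where fewer than 10 genes passed, and up to 4 members of each list described, by p. Gene models without an approved name, olfactory and vomeronasal receptors, immune receptor segments and Mup genes were counted but replaced by the next gene. The text says where another gene was chosen after its values were seen.

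The procedure was tested on simulated data with 200 changed genes among 10069. For null against wild type it recovered 50.5% of genes changed by 0.3 on the log2 scale, 89.1% at 0.5 and 98.7% at 1, and 4.07% of its calls were false. A further list of genes, lowered by 0.3 in the same data, was left out of both the 200 and the false calls. The simulated genes were drawn independently of each other, while real genes are correlated. No arrays were identical, and the smallest SD of the difference between any of the 105 pairs of arrays was 0.127. Every array was counted as 1 animal. This check finds only copied arrays and does not show that the animals were unrelated. Names of arrays here give the genotype and the replicate number of the sample title. Each sample also carries a description of the form number, dot, number; its meaning is not given, and the part before the dot is called the label number.

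Because null and heterozygous animals are both compared with the same wild-type arrays, the correlation of the fold changes is given beside 100 simulations of unchanged groups with each group's own spread, and with the wild-type arrays split between the comparisons. Alternatives fixed beforehand were no filter, a stricter filter, all probe sets, requantiling or median centring of the arrays, fits to the 2 genotypes compared, a variance trend with robust moderation, array weights, a linear model without moderated variances, a block for the replicate number, the label number as a random block or a covariate, wider and narrower neighbourhoods of Add1, camera on ranks, and leaving out each array in turn. After the data were seen, 5 more were added. They leave out the 2 null arrays with Xist signal, take that signal as a covariate, take the mean of neural markers as a covariate, leave out null array 1 and heterozygous array 1, or take the difference between lists of clock genes as a covariate. Figures were drawn with matplotlib 3.10.9.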

Results

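RNA of the choroid plexus, the tissue whose epithelium secretes cerebrospinal fluid, was profiled on 15 whole-transcript arrays. The mice had 2, 1 or 0 wild-type alleles of Add1, with 5 animals per genotype. Animals were taken at 3 weeks, before hydrocephalus develops, so that expression preceding it could be compared between genotypes. Across the 10069 tested genes the arrays correlated with each other at r between 0.955 and 0.995 (across genes, which are not independent replicates), and the median residual SD of a gene within a genotype was 0.122 on the log2 scale. The first principal component held 31.7% of the variance and ran from null array 1 (22.0) to heterozygous array 1 (-11.8), with null arrays 3, 4 and 5 at 9.42 or above and null array 2 (-0.763) next to the highest array of the other genotypes (-0.934).

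A pair of null arrays did not match the sex given in their labels. Xist, the RNA that coats the inactive X chromosome of females, read 9.09 in null array 1 and 9.69 in null array 5 and between 3.11 and 3.88 in the other 13 arrays. The Y-linked genes Eif2s3y, Uty and Kdm5d lay between 3.19 and 4.27 in these 2 arrays and between 6.92 and 7.95 in the other 13. Heterozygous array 1 stood apart in neural transcripts: Gabra6, a receptor subunit of cerebellar granule cells, read 7.80 there and the synaptic gene Snap25 7.72. The label numbers reached 451 in wild-type, 460 in heterozygous and 483 in null animals, the lowest in null being 444, so that label number and genotype were partly aligned.

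**Figure D1:**
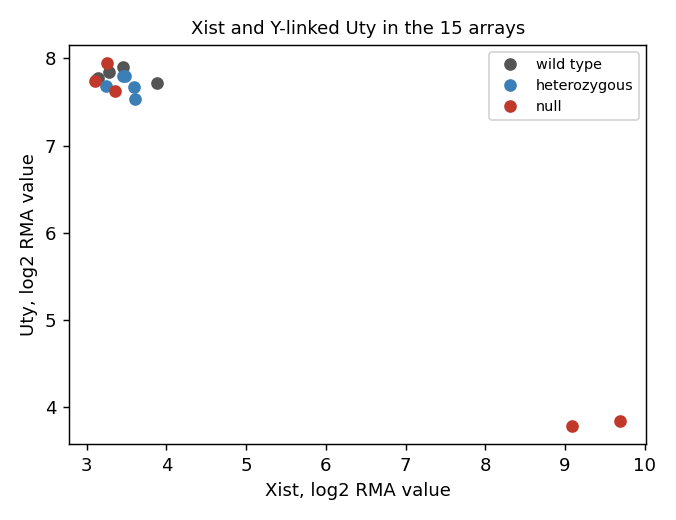
Log2 value of Xist (x axis) against that of Y-linked Uty (y axis), 1 point per array, coloured by genotype. Null arrays 1 and 5 sit at Xist 9.09 and 9.69 with Uty at 3.78 and 3.84, while the other 13 arrays have Xist at or below 3.88 and Uty at or above 7.53.

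Add1 was measured by 1 probe set. Its log2 level was 7.92 ± 0.116 in wild-type, 7.76 ± 0.0996 in heterozygous and 7.61 ± 0.161 in null animals (SD, n = 5 each), a step of 0.16 per wild-type allele. All 5 null arrays (7.41 to 7.76) lay below the lowest wild-type array (7.78), and the null signal was 80.6% of the wild-type signal (log2 difference -0.31, SE 0.0791, limma adjusted p = 0.024; exact permutation p = 0.00794, the smallest possible). The heterozygous mean was 0.16 below wild type (exact permutation p = 0.0635), and null was 0.16 below heterozygous (exact permutation p = 0.143). A probe set that covers a whole transcript can keep signal from parts outside a deletion, so the remaining signal in null animals does not measure the protein. The heterozygous difference from wild type had an exact permutation p between 0.0397 and 0.0476 without heterozygous array 4 or wild-type array 3 or 4, and that of null from heterozygous a p of 0.0476 without null array 3 (difference -0.19).

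**Figure D2:**
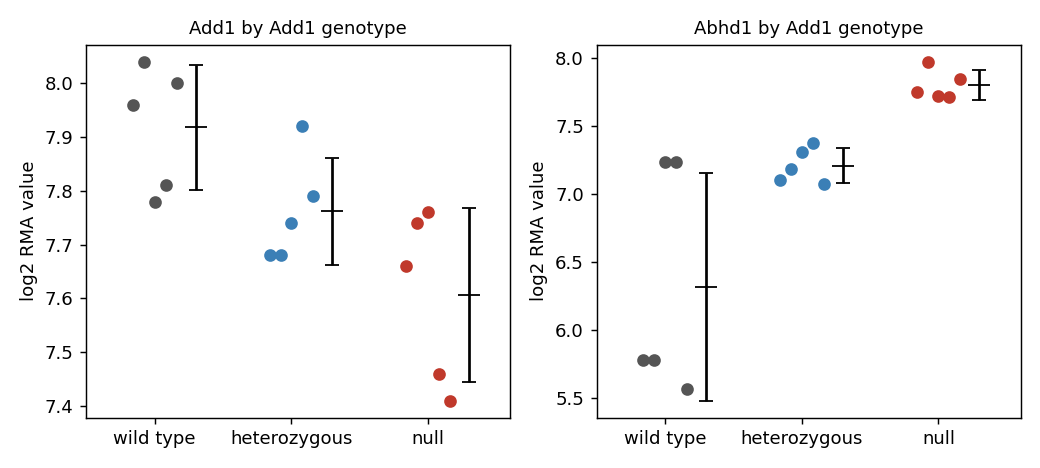
Log2 values of Add1 (left) and Abhd1 (right) in each of the 15 arrays by Add1 genotype; points are arrays and bars the mean with its SD (n = 5). Add1 fell from a mean of 7.92 in wild type to 7.61 in null; for Abhd1, wild-type arrays 3 and 4 (7.23) lie at the level of the heterozygous arrays and the other 3 between 5.57 and 5.78.

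Null against wild type addressed what the loss of Add1 changes before hydrocephalus. The largest rise was in Wfikkn2, a secreted protein with protease inhibitor domains that is a marker of choroid plexus epithelium, from 8.19 ± 0.210 to 9.83 ± 0.584 (SD, n = 5 each), or 3.10-fold (adjusted p = 4.02e-04). Rlbp1, the cellular retinaldehyde-binding protein, rose 2.74-fold with the smallest p of all genes (5.05 ± 0.183 to 6.50 ± 0.126, adjusted p = 7.49e-08). Rlbp1, Penk, Rimklb, Wif1 and Sult1c2 had wild-type means between 5.01 and 5.22, below the filter value of 5.33, where folds on arrays are compressed. The deepest fall was in Nefh, the heavy neurofilament subunit, from 7.09 ± 0.241 to 5.72 ± 0.396, a log2 difference of -1.37 (adjusted p = 3.26e-04). Secreted factors and receptors among the rises were the Wnt inhibitor Wif1 (2.11-fold), the opioid precursor Penk (2.41-fold), the stem cell factor receptor Kit (2.25-fold) and the imprinted Notch-like ligand Dlk1 (2.16-fold).

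Rises of enzymes and a transporter were Gpx3, the extracellular glutathione peroxidase (2.55-fold), Rimklb, which joins glutamate to N-acetylaspartate (2.32-fold), the proline transporter Slc6a20a (2.13-fold), the sulfotransferase Sult1c2 (2.01-fold) and the polyamine regulator Azin2 (1.94-fold). Abhd1, a hydrolase-domain gene on the chromosome of Add1, rose by 1.48 on the log2 scale, but its wild-type arrays split into 3 between 5.57 and 5.78 and 2 at 7.23. The falls included Sdf2l1 (-0.95) and Manf (-0.79) of the endoplasmic reticulum, the cytosolic heat shock protein Hsph1 (-0.79) and the Hsp90 co-chaperone Chordc1 (-0.73). Other falls were the focal adhesion protein Tns4 (-0.99), the cytochrome oxidase subunit Cox7a1 (-0.99), the circadian repressor Ciart (-0.97), the leukotriene C4 synthase Ltc4s (-0.86), Ceacam16 (-0.75), the melanocortin receptor accessory protein Mrap2 (-0.73) and the histone gene H2bc4 (-0.71), whose sequence resembles that of other H2B genes. In 17 of the 24 genes the 5 null and 5 wild-type arrays did not overlap; Penk, Slc6a20a, Wif1, Ciart, Sdf2l1, Ltc4s and Mrap2 overlapped.

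In all, limma called 778 of 10069 genes between null and wild type, 420 higher and 358 lower in null, with a median absolute log2 difference of 0.343; 84 changed by at least 1.5-fold, 60 up and 24 down. The arrays of the 2 genotypes did not overlap for 600 of all tested genes, or 5.96%, where chance gives 0.794%. After median centring of the arrays, 373 were higher and 508 lower. The count was 390, 443 or 450 without wild-type array 1, 2 or 3, 400 or 438 without null array 1 or 3, and 1418 without null array 2. Without the 2 null arrays with Xist signal, a fit chosen after the data were seen, it was 396, of which 346 were among the 778, and with Xist signal as a covariate, also chosen then, it was 240. With the label number as a linear covariate it was 257. Leaving out 1 array ended the call of only 1 of the 24 named genes, Penk, without wild-type array 1, 2 or 5 or null array 1, 3 or 4 (log2 difference 1.06 to 1.25, adjusted p 0.0553 to 0.0903).

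**Figure D3:**
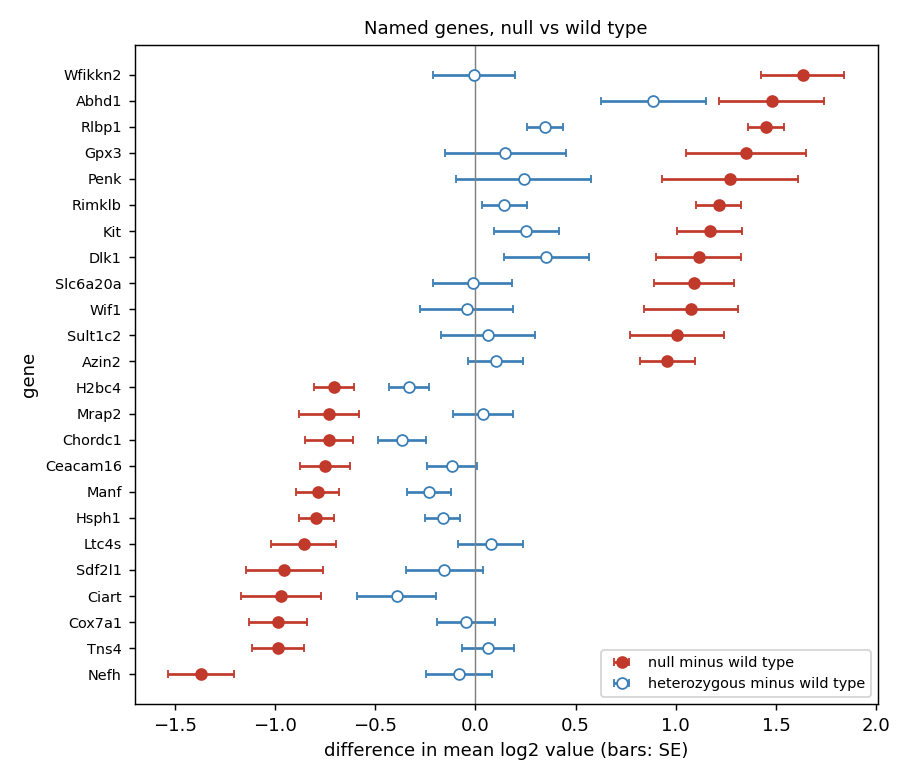
Difference in mean log2 value from wild type (x axis) for the 24 named genes (y axis), in null (filled) and heterozygous animals (open), with the SE from the linear model; n = 5 per genotype. Null differences run from -1.37 (Nefh) to 1.63 (Wfikkn2), and all 24 passed in null, while 0 passed in heterozygous animals.

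Genes of the unfolded protein response, which carry the folding capacity of the endoplasmic reticulum, fell together in null animals. Of 22 measured members 14 fell and 0 rose, 19 fell when adjusted over the list alone, and the median log2 difference was -0.41 (camera adjusted p = 2.92e-16; adjusted p = 0.0191 with an estimated correlation). The smallest p-values were those of Manf, the calcium-binding chaperone Calr (-0.42), the Hsp70 of the endoplasmic reticulum Hspa5 (-0.36) and the disulfide isomerase Pdia6 (-0.42). Nuclear genes of oxidative phosphorylation also fell, 16 of 45 with 0 rising, and 33 when adjusted over the list alone (median -0.21, camera adjusted p = 4.63e-18). This camera call was lost with an estimated correlation (adjusted p = 0.319), and fry gave a fall with an adjusted p of 0.0117. The smallest p-values belonged to Ndufb9 of complex I (-0.43), Cox5b of complex IV (-0.31), the Rieske protein Uqcrfs1 of complex III (-0.36) and Ndufa4 (-0.24).

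**Figure D4:**
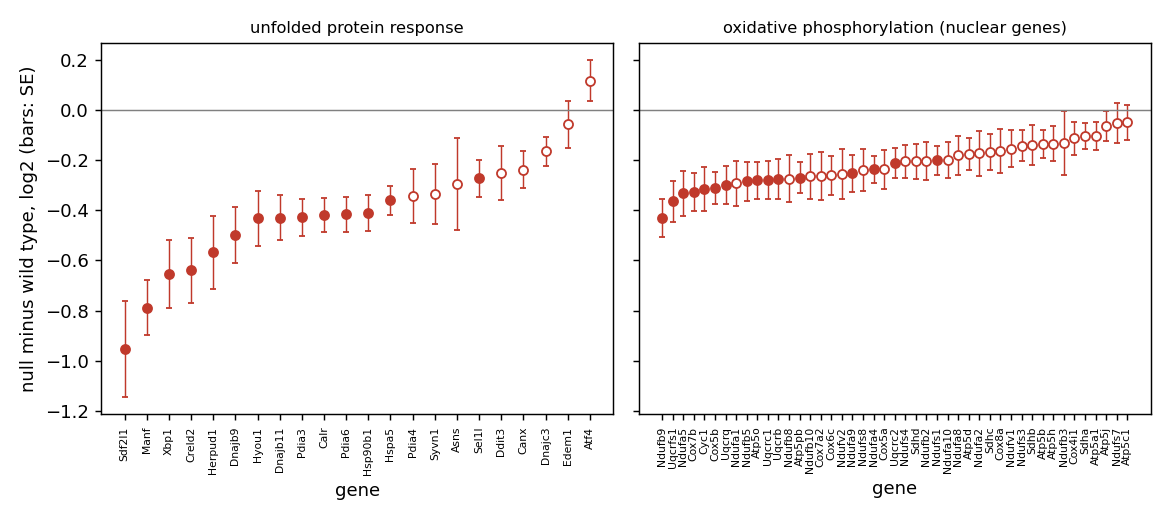
Log2 difference between null and wild type (y axis, bars SE, n = 5 per genotype) for each measured gene (x axis) of the unfolded protein response list (left, 22 genes) and the oxidative phosphorylation list (right, 45 genes). Filled points passed an adjusted p of 0.05 over all tested genes, 14 on the left and 16 on the right; the medians are -0.41 and -0.21.

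Among ion and water transport genes of cerebrospinal fluid secretion, 5 of 29 rose and 2 fell, 5 and 3 when adjusted over the list alone. The phosphate transporter Slc20a2 rose by 0.58, the water channel Aqp1 by 0.34, the kinase Wnk4, a regulator of cation-chloride cotransport, by 0.71 and the organic anion transporter Slc22a8 by 0.46; the list's camera adjusted p was 0.495 (median 0.02). Of 32 choroid plexus epithelial markers 5 rose and 3 fell, the same numbers as when adjusted over the list alone, among them Wfikkn2, Aqp1, the lactate transporter Slc16a8 (0.56) and the potassium channel subunit Kcne2 (-0.24). Their median was -0.03 and their mean 0.06, with a camera adjusted p of 0.870. The call of Kcne2 was lost without wild-type array 1 or 2 or null array 1 or 3 (-0.24 to -0.21, adjusted p 0.0576 to 0.0733). Among junction genes 3 of 31 rose, including the scaffold Tjp1 (0.45) and the polarity gene Pard6b (0.41), and Mpdz, a junctional scaffold, fell (-0.22); the numbers were the same when adjusted over the list alone (camera adjusted p = 0.104).

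Motile cilia genes moved both ways: Cfap54 (0.52) and Ccdc153 (0.53) rose, and 4 of the 39 fell, including the dynein intermediate chain Dnaic1 (-0.47); 3 rose and 8 fell when adjusted over the list alone (camera adjusted p = 0.559). Without wild-type array 1 the call of Dnaic1 was lost (-0.43, adjusted p = 0.0539). In the membrane skeleton list, to which adducin belongs, the glucose transporter Slc2a1, which binds adducin in red cells, rose by 0.58 and Mpp1 differed by -0.32 (1 up and 1 down of 16, the same when adjusted over the list alone; camera adjusted p = 0.613). The Mpp1 call was lost without wild-type array 1, 2 or 3 or null array 1 or 3 (-0.31 to -0.26, adjusted p 0.0662 to 0.0751). Of 34 actin regulators 1 rose, Capg (0.38), also when adjusted over the list alone, and the call was lost without null array 1 (0.32, adjusted p = 0.0564; camera adjusted p = 0.783). Among 31 genes tied to hydrocephalus in mice or people, Mpdz fell and Ptch1, the hedgehog receptor, was 0.20 higher (camera adjusted p = 0.613; 3 rose and 1 fell when adjusted over the list alone). The Ptch1 call was lost in 12 of the 15 fits that left out 1 array (0.17 to 0.22, adjusted p 0.0501 to 0.126).

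Astrocyte and radial glia markers were higher, 3 of 13 and 6 when adjusted over the list alone, with Sox2 (0.35) and the intermediate filament gene Vim (0.72) among them (median 0.37, camera adjusted p = 5.33e-04; adjusted p = 0.293 with an estimated correlation). The median was 0.58 without null array 5 (adjusted p = 3.43e-04), and the call was lost with the clock gene covariate chosen after the data were seen (0.14, adjusted p = 0.131). The third, Fgfr3 (0.37), lost its call in 11 of the 15 fits that left out 1 array (0.30 to 0.38, adjusted p 0.0528 to 0.134). Basement membrane genes had a median of 0.13 (camera adjusted p = 0.0162; adjusted p = 0.887 with an estimated correlation), with 1 of 26, Lamb2 (0.36), passing and 0 when adjusted over the list alone. Both the list's call and that of Lamb2 were lost without wild-type array 1 (0.09 and 0.31) or 3 (0.10 and 0.28) or null array 3 (0.12 and 0.33) or 4 (0.10 and 0.36), and that of Lamb2 also without null array 1 (0.35). Stromal genes Fbln1 (0.64), Dcn (0.68) and Pdgfra (0.79) rose and Ogn was lower (-0.59), 3 up and 1 down of 19, also when adjusted over the list alone (median 0.14, camera adjusted p = 0.104). With the preset correlation the stromal list passed without null array 1 (0.21, adjusted p = 0.0174) or wild-type array 5 (0.28, adjusted p = 0.00249); over all arrays its adjusted p was 0.887 with an estimated correlation. The call of Ogn was lost without wild-type array 3 or null array 1 or 3 (-0.55 to -0.45, adjusted p 0.0576 to 0.0692). Of 10 endothelial markers 2 rose, also when adjusted over the list alone, with the VEGF receptor Kdr at 0.49 (camera adjusted p = 0.451). Of 8 neuron markers Nefh fell and the imprinted RNA Meg3, from the locus of Dlk1, was 0.80 higher (median 0.02, mean -0.08, camera adjusted p = 0.630; 1 up and 1 down when adjusted over the list alone). The call of Meg3 was lost without wild-type array 1, 2 or 3 or null array 1 or 3 (0.63 to 0.83, adjusted p 0.0619 to 0.101).

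In the immediate early and heat shock list Hsph1 fell, Hspa1a was lower (-0.51) and Klf6 higher (0.26), 1 up and 2 down of 19, also when adjusted over the list alone (camera adjusted p = 0.613). The calls of Hspa1a and Klf6 were lost without wild-type array 2 or null array 3, that of Hspa1a also without wild-type array 1, and that of Klf6 also without wild-type array 3 or 4 or null array 1 (-0.48 to -0.45 and 0.20 to 0.25). No member was called, over all genes or adjusted over the list alone, among 6 pericyte and smooth muscle markers (median 0.16), 6 macrophage markers (0.04), 9 cerebellar neuron markers (-0.39), 10 oligodendrocyte markers (0.01), 6 erythroid genes (-0.001), 15 interferon response genes (-0.07), 6 inflammation genes (0.04) and 7 cell cycle genes (0.10). The camera adjusted p of these 8 lists lay between 0.315 and 0.870.

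Heterozygous against wild type addressed whether 1 allele suffices to keep the wild-type profile. Among genes with an approved name, the smallest p-values belonged to Spred2 (-0.29) and Spry2 (0.25), both inhibitors of Ras signalling, Bckdhb, a subunit of branched-chain ketoacid dehydrogenase (-0.29), the nucleotide kinase Cmpk1 (-0.29), Mrps10 (0.32), Rlbp1 (0.35), Pym1 (0.22), Tent5a (0.31), Slc66a1 (0.24) and the mitochondrial chaperone Trap1 (0.18). Each had an adjusted p of 0.994. Rlbp1, at 5.39 ± 0.147 (SD, n = 5), lay between wild type and null. limma called 0 genes, with 381 at an unadjusted p under 0.05 and a linear model without moderated variances also called 0. The smallest adjusted p was that of the gene model Gm5771 (0.50, SE 0.0807, adjusted p = 0.0875), named after its values were seen, which passed without wild-type array 4 (0.56, adjusted p = 0.0146) and with array weights (0.51, adjusted p = 0.0152). The unfolded protein response list had a median of -0.08 (camera adjusted p = 3.11e-04) and the interferon response list one of 0.11 (camera adjusted p = 0.0154), each with 0 members passing, also when adjusted over the list alone. Both camera calls were lost with an estimated correlation (adjusted p = 0.870 for each), and the interferon call also without heterozygous array 5 (0.05, adjusted p = 0.447). Other lists passed with the preset correlation when 1 array was left out. Over all arrays their adjusted p with an estimated correlation was 0.998 for oxidative phosphorylation and 0.870 for the other 5. Endothelial markers passed without wild-type array 1 (-0.12) or 2 (-0.08) or null array 5 (-0.07), stromal markers without wild-type array 1 (-0.13) or heterozygous array 4 (-0.14), and oxidative phosphorylation genes without heterozygous array 1 or wild-type array 4 (-0.03 for both) or 5 (-0.02). In heterozygous array 1 the mean deviation of neuron markers was 1.15, of cerebellar neuron markers 1.29 and of oligodendrocyte markers 0.90, and in the other 4 heterozygous arrays at most 0.02. Neuron and cerebellar neuron markers passed without heterozygous array 4 (0.30 and 0.19) or 5 (0.32 and 0.23) or wild-type array 4 (0.28 and 0.12). Oligodendrocyte markers passed without those 3 arrays (0.25 to 0.30), heterozygous array 2 (0.27) or 3 (0.24) or null array 5 (0.20). In simulated data this comparison recovered 53.3% of genes changed by 0.3 and 91.5% of those changed by 0.5, so many differences under 0.3 would not be detected with 5 arrays per group.

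Null against heterozygous asked what the loss of the second allele changes. Wfikkn2 (3.12-fold), Wif1 (2.17-fold), Rlbp1 (2.15-fold), Slc6a20a (2.15-fold), Rimklb (2.10-fold), Kit (1.89-fold), Gpx3 (2.30-fold) and Sult1c2 (1.92-fold) rose here too. The null arrays are those compared with wild type, so this recurrence is not independent. Log2 differences of these comparisons correlated at r = 0.875 across genes, where simulated unchanged groups gave 0.648 through the shared null arrays. Further rises over heterozygous animals were Slc26a7, an anion exchanger (2.10-fold), the elastic fibre protein Fbln5 (1.93-fold), the matrix proteoglycan Bgn (1.92-fold) and the centrosomal gene Cep290 (2.04-fold). Cep290 was low in heterozygous animals (4.81, against 5.66 in wild type and 5.84 in null) and did not pass between null and wild type (0.18, SE 0.290, adjusted p = 0.750). Nefh (-1.29), Tns4 (-1.05), Cox7a1 (-0.94), Ltc4s (-0.93), Sdf2l1 (-0.80), Mrap2 (-0.77), the axon guidance gene Nav3 (-0.67), Ceacam16 (-0.63), the insulin gene Ins2 (-0.63), Slc35f1 (-0.63), Hsph1 (-0.63) and the cilia gene Cfap52 (-0.62) fell. Leaving out 1 array ended the call of Cep290 in 8 of 15 fits (0.91 to 1.03, adjusted p 0.0506 to 0.0926) and of Cfap52 in 10 (-0.65 to -0.59, adjusted p 0.0521 to 0.0951), which was -0.40 without null array 1. It also ended that of Gpx3 without heterozygous array 3 (1.18, adjusted p = 0.0516), of Sult1c2 without heterozygous array 1 (0.83, adjusted p = 0.0598) and of Sdf2l1 without null array 1 or 3 (-0.68 and -0.72, adjusted p 0.0592 and 0.0559).

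limma called 798 genes here, 435 higher and 363 lower in null, and 79 of at least 1.5-fold (44 without null array 1, 122 without null array 2). After median centring of the arrays 440 were higher and 492 lower, and after requantiling 459 and 496. The count was 454, 519 or 432 without heterozygous array 1, 2 or 3, 356 or 402 without null array 1 or 3, 1815 without null array 2, and 330 without the 2 null arrays with Xist signal. It was 195 with the label number as a linear covariate and 158 with Xist signal as a covariate. The unfolded protein response list fell, 8 of 22 members with 0 rising and 17 when adjusted over the list alone, with a median of -0.30 (camera adjusted p = 2.98e-10; adjusted p = 0.104 with an estimated correlation). Oxidative phosphorylation genes fell in 12 of 45 cases with 0 rising, 32 when adjusted over the list alone (median -0.21, camera adjusted p = 7.93e-15; adjusted p = 0.594 with an estimated correlation). Stromal genes had 4 rises of 19, with Dcn at 0.83 and Pdgfra at 0.88, and 7 up and 1 down when adjusted over the list alone (median 0.21, camera adjusted p = 0.0149; adjusted p = 0.651 with an estimated correlation), a call lost without null array 4 (0.10, adjusted p = 0.142); the median was 0.14 without heterozygous array 3. Astrocyte and radial glia markers had 3 rises of 13, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.0149; adjusted p = 0.594 with an estimated correlation). That call was lost without heterozygous array 5 or null array 3 or 4 (0.11 to 0.12, adjusted p 0.0537 to 0.0838), and the median was 0.42 without heterozygous array 1, 0.30 without null array 1 and 0.34 without null array 5. Endothelial markers had 2 rises of 10, Kdr (0.52) and Cdh5 (0.74), also when adjusted over the list alone (median 0.19, camera adjusted p = 0.0403; adjusted p = 0.651 with an estimated correlation). Basement membrane genes had 1 of 26 higher and 0 when adjusted over the list alone (median 0.11, camera adjusted p = 0.0403; adjusted p = 0.651 with an estimated correlation). Interferon response genes had 1 of 15 lower, and 1 up and 4 down when adjusted over the list alone (median -0.13, camera adjusted p = 0.0405; adjusted p = 0.651 with an estimated correlation). These 3 calls were also lost without heterozygous array 1 or 5 or null array 2, 3 or 4, that of the basement membrane list also without heterozygous array 2 and that of the interferon list without null array 5. In these fits the medians were 0.14 to 0.21 for endothelial, 0.09 to 0.11 for basement membrane and -0.18 to -0.09 for interferon response genes. The endothelial median was 0.32 without null array 5, and the interferon median -0.20 without heterozygous array 2. The interferon member called was Ifi35 (-0.23, limma adjusted p = 0.0491). It lost its call in 13 of the 15 fits that left out 1 array (-0.24 to -0.18, adjusted p 0.0563 to 0.106). Heterozygous array 1, with its neural signal, is in this comparison, and cerebellar neuron markers had a median of -0.78 with 0 of 9 called, also when adjusted over the list alone (camera adjusted p = 0.115). With the preset correlation, neuron markers passed without heterozygous array 4 (-0.33), and cilia genes (-0.05) and pericyte markers (0.27) without null array 5. Over all arrays their adjusted p with an estimated correlation was 0.651, 0.763 and 0.651.

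The slope on the number of Add1 alleles was called for 568 genes, 252 rising and 316 falling with each added wild-type allele. With 5 arrays per genotype it equals the difference between wild type and null divided by 2, whatever the heterozygous level, which enters only through the residual spread. It is therefore no separate test of gene dose, and its calls, all 568 also made between null and wild type, are not independent of that comparison. After median centring the split was 367 rising and 265 falling. The count was 247, 273 or 322 without wild-type array 1, 2 or 3, 199 or 162 without null array 1 or 3, and 1 with the label number as a linear covariate. Add1 itself had a slope of 0.16 per allele (SE 0.039, adjusted p = 0.0276).

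Heterozygous animals departed from the midpoint of null and wild type in 6 genes, which are named after their values were seen. Gm5771 (0.46) and the ribosome assembly gene Mrto4 (0.42) lay above the midpoint, and Fbln5 (-0.53), the amino acid transporter Slc6a15 (-0.52), Bckdhb (-0.36) and Cmpk1 (-0.36) below it, with adjusted p-values from 0.0268 to 0.0438. The count was 0 without wild-type array 1, heterozygous array 2 or 4 or null array 3, and 1, 3 or 2 without heterozygous array 1, 3 or 5. It was 3 without wild-type array 3 or 4 and 126 without null array 2.

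Calls shared by null against wild type and heterozygous against wild type numbered 0, since the latter had none. The log2 differences of these comparisons correlated at r = 0.225 across genes, below the r of 0.370 that unchanged groups give through the shared wild-type arrays. The covariance was 0.00348 beside 0.00304 in the simulations (SD 1.47e-04), a difference of 4.42e-04. The simulations drew each gene independently, while real genes are correlated, so their SD is too small to judge this difference by. When the wild-type arrays were split between the comparisons, r was 0.0342 on average (-0.0491 to 0.0745 over the splits). The 50 tested genes nearest to Add1 on its chromosome, 25 on each side, held 2 rises and 1 fall between null and wild type (camera p = 0.949; 6% called against 7.73% of all genes, Fisher's exact p = 1). None of these neighbours was called between heterozygous and wild type, as no gene was.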

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

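The tests of the 2 arrays with Xist signal and of their Add1 level, and both tests of Abhd1, were chosen only after these values were seen, as was the choice of Fkbp5 and Zbtb16, and the clock gene lists were written after Arntl, Dbp, Ciart and Per1 had been seen.

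Xist read 9.09 in null array 1 and 9.69 in null array 5, against at most 3.88 in the other 13 arrays, in a series labelled male. Eif2s3y, Uty and Kdm5d in these 2 arrays lay at least 2.70 log2 units below the lowest of the other 13, as a sample from a female would read and a mixture of male and female tissue would not. That they are mislabelled wild-type animals is argued against by Add1, which reads 7.66 and 7.41 in the 2 arrays, below the lowest wild-type array (7.78). Add1 cannot tell null array 1 from a heterozygous animal, as the lowest heterozygous array read 7.68. Null arrays 2 and 3 (7.74 and 7.76) lay inside the heterozygous range. No wild-type or heterozygous array has Xist signal, so sex is partly aligned with genotype. The 2 arrays may come from female animals, which are null if their genotype labels are right. The 2 arrays were weighed as a source of the 778 calls. Over these genes the ratio of the log2 difference without them to that with them had a median of 0.898 (interquartile range 0.783 to 1.02). The 778 were called with the 2 arrays included, which favours differences shared by all null arrays. The ratio therefore cannot exclude the 2 arrays as a source of calls. Only 396 genes passed without them, and the 346 of these among the 778 do not rest on the 2 arrays.

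The fall of the unfolded protein response list in null animals kept a median of -0.345 without the 2 arrays with Xist signal and of -0.359 without null array 1, so neither accounts for most of it; null array 1 lies farthest from the other arrays and also stands apart in the glucocorticoid-responsive genes Fkbp5 (8.14, others 5.64 to 6.80) and Zbtb16 (7.73, others 5.03 to 6.15). A different time of day at dissection was weighed because Arntl (0.53), Cry1 (0.40) and Nfil3 (0.32) were higher and Dbp (-0.47) and Ciart (-0.97) lower in null, although leaving out 1 array ended the call of Cry1 in 9 of 15 fits (0.36 to 0.44), of Nfil3 in 11 (0.26 to 0.34) and of Dbp in 6 (-0.45 to -0.38); the difference between lists of clock genes was 0.298 ± 0.190 in null and -0.157 ± 0.176 in wild-type animals (SD, n = 5 each), which partly restates those genes. With that difference as a covariate the median of the list was -0.318, against -0.413 without it (mean of the list -0.315, SE 0.0763). The difference did not overlap between null (lowest 0.106) and wild-type animals (highest 0.005). The fall thus remained with this covariate, but the fit cannot separate clock phase from genotype. The covariate ended most single calls, leaving 13 calls, 12 of them among the 778 genes. Over the 778, the log2 difference with the covariate had a median of 0.961 times that without it (interquartile range 0.783 to 1.13). The SE had a median of 1.57 times. The list also stayed at -0.366 with the label number as a linear covariate (camera adjusted p = 6.96e-10, highest over all alternatives 0.0191). That number is partly aligned with genotype and its meaning is not given, so the covariate cannot settle a cohort effect. Heterozygous array 5 and null array 2 share the label number 460. The mean deviation of the list was -0.045 in the former and -0.126 in the latter. It was 0.06 to 0.128 in the other heterozygous arrays, 0.133 in wild-type array 5 (451) and -0.329 in null array 1 (444). The fit without the Xist arrays argues against sex. A response to the loss of Add1, clock phase, and differences in cohort or handling remain open.

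Abhd1, with 42 tested genes between it and Add1 on the same chromosome, takes stepped levels: 5.57 to 5.78 in 3 wild-type arrays, 7.07 to 7.37 in the heterozygous arrays and 7.71 to 7.97 in null. Wild-type arrays 3 and 4, the only wild-type arrays with label number 432, read 7.23, inside the heterozygous range. A response to the loss of Add1 alone would not give this if their genotype labels are right. Add1 read 7.78 and 7.81 in these 2 arrays, inside its heterozygous range (7.68 to 7.92). It read 7.96 to 8.04 in the other 3 wild-type arrays. A wrong genotype label for the 2 arrays was not tested and stays open. As a hypothesis, a variant of Abhd1 or its surroundings may be carried on the chromosome of the targeted allele, separated from it by recombination in the line of the 2 exceptional animals. If its copies add up, the heterozygous mean should lie near the middle on the linear scale, and it lay at 0.561 of the way from the 3 low wild-type arrays to null (SD 0.0791 over the 5 heterozygous arrays). Of the tested genes on either side of Abhd1, Khk was higher in null than in wild type (0.45, limma adjusted p = 0.0117). Preb did not pass (0.08, limma adjusted p = 0.477). No genotype outside Add1 is among the labels, so this hypothesis stays untested beyond these values.

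Single arrays stood apart from the other 4 of their group in 24 of 309 tests over 80 genes and 23 lists, where chance gives about 15.4, and 5 of the 24 were in heterozygous array 1. In that array Penk read 6.34 (others at most 5.26), Sult1c2 4.75 (others at least 5.24), and the mean deviation of the neuron list was 1.15, of the cerebellar neuron list 1.29 and of the oligodendrocyte list 0.90, with the other 4 arrays at or below 0.02. In other heterozygous arrays, Sdf2l1 read 8.16 and Slc66a1 6.13 in array 5, and Slc16a8 8.66, Fbln1 7.88 and the hydrocephalus list 0.03 in array 4. In wild-type animals, array 1 stood apart for Bckdhb (7.73) and Capg (5.83), array 2 for Tns4 (6.68), array 3 for Cmpk1 (8.44) and Wnk4 (5.15), array 4 for Wif1 (5.77), and array 5 for Slc22a8 (8.33), the macrophage list (0.29) and the erythroid list (-0.16). In null animals, Hsph1 read 8.24 in array 1 and Cep290 4.63 in array 2, the stromal list stood at 0.50 in array 4, and the actin list (-0.04) and the pericyte list (-0.35) were low in array 5.

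Other splits of the 10 or 15 arrays were drawn 100 at a time, the real one included. For null against wild type, 1 split of 100, the real one, reached 778 calls and the highest other gave 331. For null against heterozygous it was also 1 of 100, with 798 calls and a highest other of 610. A random split of the arrays would thus seldom reach either count. Label number and sex are partly aligned with genotype, so the splits cannot tell genotype from these. The slope on allele number (1 of 100, 568 calls, highest other 125) and the midpoint (1 of 100, 6 calls, highest other 1) were split over all 15 arrays. Such splits also move the differences between null and wild type into the spread, which lowers their counts. They leave chance open for the midpoint and are no separate evidence for the slope, which restates null against wild type. For heterozygous against wild type the real count was 0, which all 100 splits reach by construction (highest other 1), so they decide nothing.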

How the results depend on the processing

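The fits without the Xist arrays, with Xist signal, neural markers or clock genes as covariates, and without the 2 arrays farthest from the others were chosen after the data were seen. The other fits were fixed beforehand. Over 181 named gene results, 5913 refits gave 5249 on the same side of the threshold, 610 that lost the call, 54 that gained it and 0 that reversed. For the lists, 2229 of 2343 refits stayed on the same side, 62 lost and 52 gained the call, and 0 reversed. Where no cause is given below, the cause was not tested.

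Counts are given for null against wild type (778), null against heterozygous (798), the slope (568) and the midpoint (6), where they moved by over 1.5 times. No filter gave 500 for null against heterozygous, 322 for the slope and 0 for the midpoint. All probe sets gave 338 for the slope and 0 for the midpoint. Fits to only the 2 genotypes, with fewer arrays, gave 461 and 343. Array weights gave 1320, 1297 and 78 (midpoint), and 1 for heterozygous against wild type (0). A linear model without moderated variances gave 493, 469, 204 and 0. The label number as a random block gave 313 for the slope, and as a linear covariate 257, 195 and 1 (slope). Without the Xist arrays the counts were 396, 330, 117 and 2, and with Xist signal as a covariate 240, 158, 41 and 1; each gave 1 for heterozygous against wild type. Without the 2 farthest arrays they were 481, 223, 286 and 2, and with the clock covariate 13, 5, 1 and 0. Leaving out 1 array gave 390 to 1418, 356 to 1815, 162 to 697 and 0 to 126, and 0 to 1 for heterozygous against wild type.

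Genes of at least 1.5-fold numbered 84 for null against wild type and 79 for null against heterozygous. The latter was 49 with the stricter filter, 121 over all probe sets, 48 with Xist signal as a covariate, 41 without the 2 farthest arrays, and 44 to 122 when 1 array was left out. With the clock covariate they were 11 and 5.

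The replicate number is shared by title across genotypes but does not pair the arrays. Of 15 same-numbered pairs 4 correlated over 0.1 in their deviations (mean r -0.023), and 1 array correlated best with its own number. With the replicate number as a block the counts were 518, 550, 306 and 1.

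Add1 kept its direction in every refit. The heterozygous level was -0.149 (exact permutation p = 0.0317) after requantiling and -0.166 (p = 0.0238) after median centring, and ranged from -0.196 to -0.126 when 1 array was left out. Null against heterozygous was -0.173 and -0.168 (exact p = 0.0397 for both), and -0.194 to -0.107 when 1 array was left out. There is 1 Add1 probe set, so no other could be compared.

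Between null and wild type, the unfolded protein response list stayed called in all 34 alternatives (median -0.435 to -0.318, adjusted p at most 0.0191). With an estimated correlation the oxidative phosphorylation (-0.21), astrocyte (0.368) and basement membrane lists (0.131) lost the call. With the clock covariate the astrocyte list was 0.136 and the basement membrane list 0.0234; the latter was also lost with the label number as a covariate (0.0974) and ranged from 0.087 to 0.18 when 1 array was left out. The correlation between the 2 comparisons with wild type moved from 0.225 to 0.0342 when the wild-type arrays were split, by construction. Signal near the background limits what can be measured, and the filter, met by 5 of 15 arrays, does not remove all such genes.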

Other observations

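The genes below were looked at after their values had been seen. After Hsph1 and Chordc1 had been seen to fall, a list of other heat shock chaperones was written to ask whether a wider fall may be present. It was written before it was tested as a list, but Hsp90aa1, Hspb1 and Dnajb1 had already been tested in the immediate early and heat shock list. The arrays are those in which Hsph1 and Chordc1 fell, so the result is not independent of these genes. Of 21 measured members 5 fell and 0 rose (median log2 difference -0.19, camera p = 2.84e-08; p = 0.00126 with an estimated correlation). The members that fell were the Hsp90 co-chaperones Stip1 (-0.33) and Ahsa1 (-0.37), the mitochondrial chaperonin Hspd1 (-0.29) and the Hsp110 family members Hspa4 (-0.23) and Hspa4l (-0.22). Leaving out 1 array ended the call of Hspa4l in 8 of 15 fits (-0.23 to -0.18, adjusted p 0.0522 to 0.108) and of none of the other 4. The inducible Dnajb1 (-0.23, adjusted p = 0.329) and the constitutive Hspa8 (-0.08, adjusted p = 0.362) did not pass. The cold-inducible RNA-binding gene Cirbp, in contrast, rose by 0.80.

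Of 4 measured clock genes of the Bmal1 phase 3 rose, Arntl by 0.53, Cry1 by 0.40 and Nfil3 by 0.32, while Clock differed by -0.02. Of 12 genes of the opposite phase only Dbp (-0.47) and Ciart (-0.97) passed, with Nr1d1 at -0.32 (adjusted p = 0.268) and Per2 at -0.06 (adjusted p = 0.783). Only Arntl and Ciart kept their call in all 15 fits that left out 1 array. Cry1 lost it in 9 (adjusted p 0.0519 to 0.106), Nfil3 in 11 (0.0551 to 0.135) and Dbp in 6 (0.0562 to 0.0933).

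Imprinted Dlk1 and Meg3, expressed from opposite parental copies of 1 locus, were both higher in null animals, by 1.11 and 0.80. The call of Meg3 was lost without wild-type array 1, 2 or 3 or null array 1 or 3 (0.63 to 0.83, adjusted p 0.0619 to 0.101).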
